A study of Mus musculus with 5 samples.

How the data were processed

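The series holds 5 single-colour arrays, 1 per tumour, hybridised with biotin-labelled RNA from tumours that were recognised by a green fluorescent reporter of the fusion gene, per the labels' protocols. The authors deposited 1 table of log2 values for 45101 probe sets, with no missing value. The submitters' processing notes name RMA, which corrects background, quantile-normalises probes and summarises each probe set on a log2 scale; its version, the platform and the annotation are not given in the sources used here. The deposited log2 values fit that scale, running from 2.84 to 14.9. RMA removes differences in overall level between arrays, and its summaries understate folds of dim probe sets. The table gives no detection calls and no raw intensities, so a probe set at the low end has a level but no known background.

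Each tumour was placed in its group from the source description (tamoxifen-exposed female, or unexposed male). Replicate numbers follow accession order and pair nothing. The labels do not say whether each tumour came from a separate mouse. Exposed females 2 and 3 share an age of 10 months, while the other ages within a group differ. The p-values set the difference between the groups against the spread between these tumours. No scan date, slide or batch is given. The most similar pair of arrays had r = 0.980 and 117 probe sets 4-fold or more apart, so no pair looked like a single array deposited again. The number of arrays limits the precision: with 3 against 2, an exact permutation test cannot give p below 0.1.

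The plan fixed before the data were examined was to test 1 probe set per gene and 39 gene lists. This needs a table that pairs probe sets with genes. The reference used here lists gene symbols and accessions without array identifiers, and 0 of the 45037 probe set identifiers other than controls matched an entry in it. As the plan allowed for this case, the test was run over all 45037 probe sets other than 64 controls. The gene lists, the sex-linked check, the level of each list per tumour and the alternatives that average or choose probe sets by gene were not run. The naming rule took, among called probe sets with groups that did not overlap, those with the largest difference in each direction; because identifiers carry no gene name here, 2 per direction are given, and the 20 most variable ones are only counted.

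Values were used as deposited in limma 3.58.1 (R 4.3.3), with lmFit on 2 groups of 3 and 2 arrays, eBayes at its default settings, and Benjamini-Hochberg adjustment over all probe sets tested, two-sided, with a threshold of 0.05 on the adjusted p. No filter on low values was applied. Differences are exposed female minus unexposed male. The prior had 2.56 degrees of freedom. Control probe sets were tested in a second fit with all 45101 probe sets. Within-group spread is the residual SD of the same model. Simulated data were given the means of these arrays, limma's moderated variances and normal noise of equal spread in both groups (20 simulations of 45037 probe sets, 3 against 2 arrays, 200 changed per size). The procedure called 18.8% of probe sets changed by 1 log2 unit, 88.7% of those changed by 2 and 98.8% of those changed by 4. Of the calls, 6.35% were unchanged probe sets, and at most 1 call was made where nothing had been changed. The real arrays varied more among the exposed females than between the males, so these rates may not hold for them.

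Alternatives fixed before the data were examined were a second quantile normalisation, centring on the median, leaving out probe sets ending in _X_AT or _S_AT (4529, whose probes can match several transcripts), keeping only probe sets with a log2 value of 6 or more in at least 2 arrays, eBayes with trend and robust settings, array weights, a minimum log2 difference of 1, other measures of spread and distance, and omission of each tumour. With 1 male left, its spread is assumed to equal that of the females.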

Results

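Synovial sarcoma is a soft-tissue cancer that carries a fusion of the SYT gene (now SS18) with an SSX gene. The 5 tumours profiled here arose in mice in which the human fusion SYT-SSX2 is switched on by CreER, a recombinase activated by tamoxifen and expressed here from the Rosa locus. Of these tumours, 3 came from females given a single 0.1 mg/g pulse of tamoxifen at 3 months of age, and 2 came from males that received none. The exposed mice were 13, 10 and 10 months old (exposed females 1, 2 and 3), and the unexposed mice were 9 and 10 months old (unexposed males 1 and 2). RNA was hybridised to single-colour expression arrays of 45101 probe sets. The deposited log2 values had array medians from 5.96 in exposed female 3 to 6.09 in unexposed male 2. Sex and tamoxifen changed together in every tumour, so each difference between the groups is a difference in both. The sources pair no probe set with a gene except control probe sets, whose identifiers name their transcript. Genes are therefore named below only for those controls, and the sex given by the labels was not checked against sex-linked genes. The values against the males therefore rest on the labels of 2 tumours.

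The first question was how alike the tumours were, since induction was random and sporadic. The 2 unexposed male tumours resembled each other more than any other pair did, and the range of similarity among the 3 exposed female tumours overlapped the range between females and males. Across 45037 probe sets, Pearson's r was 0.980 between the unexposed males, from 0.937 to 0.955 among the 3 pairs of exposed females, and from 0.925 to 0.953 among the 6 pairs that crossed the groups. These correlations run across probe sets within pairs of arrays, and probe sets are not independent replicates. Only 117 probe sets differed 4-fold or more between the unexposed males, against 657 to 1016 between exposed females and 672 to 1193 across the groups. Exposed female 2 had r = 0.953 and 672 such probe sets against unexposed male 1, close to its r = 0.955 and 657 probe sets against exposed female 1. The pair that differed at the most probe sets was exposed female 3 and unexposed male 1, with 1193. The mean distance (1 minus r) was 0.0643 between groups and 0.0447 within them, a difference of 0.0196. An exact one-sided permutation test over the 10 splits of the arrays gave p = 0.1, the smallest value this design allows, so separation of the groups over the whole profile was not established.

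**Figure D1:**
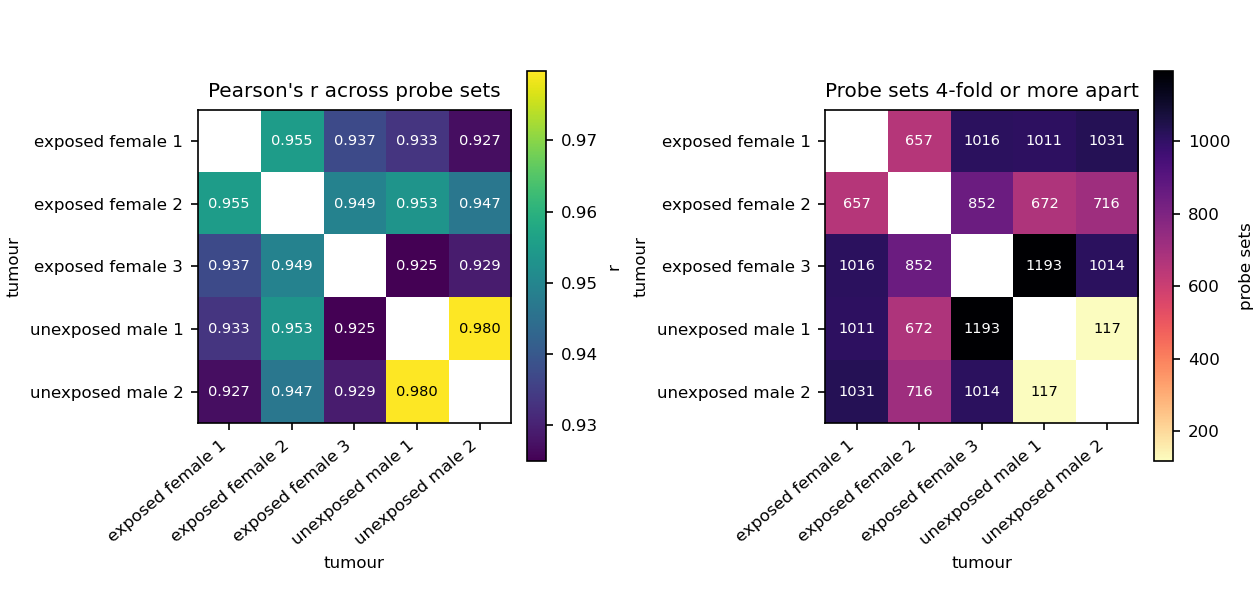
Similarity of each pair of tumours, as Pearson's r across 45037 probe sets (left, colour scale in r) and as the number of probe sets that differed 4-fold or more (right, colour scale in probe sets). Both axes list the 5 tumours; the pair of unexposed males stands apart with r = 0.980 and 117 probe sets.

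The main comparison asked which transcripts differed between tumours of tamoxifen-exposed females and of unexposed males. Most of the differences of 8-fold or more were falls in the exposed female tumours, while differences of 2-fold or more were more often rises. Group means differed 2-fold or more for 953 probe sets that were lower in the exposed females and for 1510 that were higher, and 8-fold or more for 210 probe sets that were lower in the exposed females and for 32 that were higher. At 16-fold or more the numbers were 126 and 6, and at 64-fold or more they were 15 and 0. In limma's moderated test with Benjamini-Hochberg adjustment, 241 probe sets passed an adjusted p under 0.05; 221 of them fell in the exposed females and 20 rose. The number of rises was 2 without exposed female 1, 16 without exposed female 2, 33 without exposed female 3, 0 without either male and 41 with array weights. The 221 that fell had a median log2 difference of -3.01 (quartiles -4.29 and -2.19). Of these, 53 were under 5 on every exposed array, a level not known to be above background, so the sizes of those falls are uncertain. The 20 that rose had a median of 1.52. In all 241 the values of the groups did not overlap; over all probe sets 38.0% had groups that did not overlap, where chance gives 20%. At an unadjusted p under 0.05 there were 7131 probe sets, against 2252 expected by chance and 636 to 4503 in the 9 other splits of the arrays into 3 and 2. Those splits mix exposed and unexposed tumours, so a group difference widens their residual spread and lowers their counts. They therefore do not show what would be seen with no group difference. The 7131 were split almost evenly, with 3425 lower and 3706 higher in the exposed females.

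By the naming rule, the called probe sets with the largest falls were 1447713_AT and 1426438_AT. The log2 level of 1447713_AT was 4.65 ± 0.58 (SD, n = 3) in the exposed females and 11.2 and 11.6 in the males, a log2 difference of -6.80 ± 0.36 (SE, limma adjusted p = 0.00505). The log2 level of 1426438_AT was 3.18 ± 0.12 (SD, n = 3) in the exposed females against 10.2 and 9.61 in the males, a log2 difference of -6.71 ± 0.22 (SE, limma adjusted p = 0.00445). Among called probe sets, the largest rises were those of 1453351_AT and 1446234_AT. The log2 level of 1453351_AT was 8.32 ± 0.33 (SD, n = 3) in the exposed females against 4.12 and 4.08 in the males, a log2 difference of 4.22 ± 0.23 (SE, limma adjusted p = 0.00505). For 1446234_AT the levels were 8.29 ± 0.30 (SD, n = 3) against 5.99 and 5.62, a log2 difference of 2.49 ± 0.24 (SE, limma adjusted p = 0.0236). The levels of 1426438_AT in the exposed females were close to the lowest values on the arrays (2.84 to 2.94), and those of 1453351_AT in the males and of 1447713_AT in exposed female 3 were under the lower quartile of their arrays (4.64 to 4.82). These levels are not known to be above background, so the sizes of these 3 differences may be understated, and their order by size is uncertain. The number of calls depended on which tumours were included: 108 probe sets passed without exposed female 1, 107 without exposed female 2, 257 without exposed female 3 and 0 without either unexposed male (4875 at an unadjusted p under 0.05 in limma without unexposed male 1, and 2909 without unexposed male 2). The count of 8-fold falls was steadier, at 178 to 251 over the same 5 omissions, whereas that of 8-fold rises was 16 without exposed female 1, 65 without exposed female 2 and 107 without exposed female 3.

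**Figure D2:**
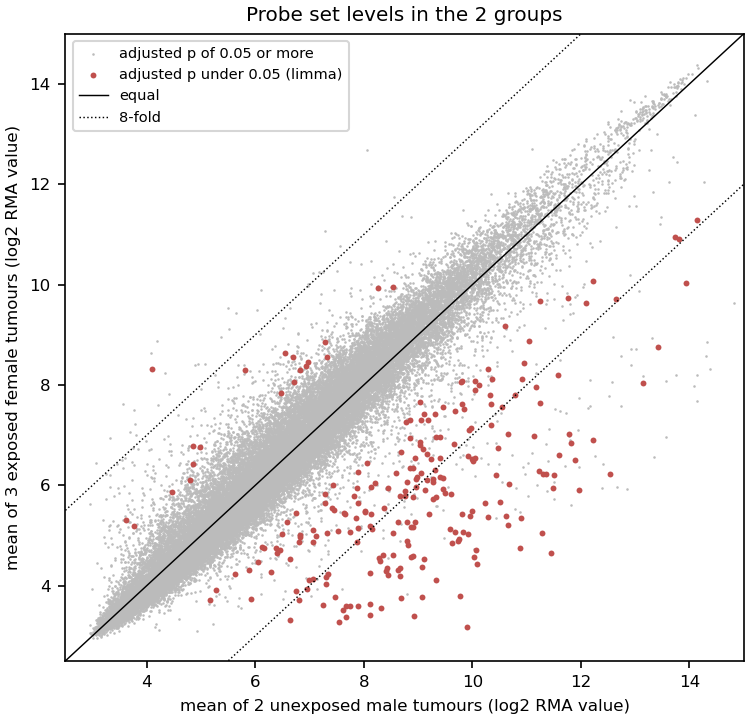
Mean log2 value of each of 45037 probe sets in the 3 exposed female tumours (vertical axis) against the 2 unexposed male tumours (horizontal axis). Red points are the 241 probe sets with a limma adjusted p under 0.05, of which 221 lie below the line of equality; dotted lines mark 8-fold differences.

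Among transcripts named on the array, the glycolytic enzyme Gapdh had the largest differences between the groups. Each of its 3 probe sets was lower in every exposed female tumour than in either male tumour, by 1.76-fold at the 3′ end, 2.09-fold in the middle and 2.31-fold at the 5′ end. The 3 probe sets measure a single transcript, and over all probe sets 38.0% had groups that did not overlap. Lower values in every exposed tumour were not particular to Gapdh among the named transcripts. They were also seen, with smaller differences, at the 5′ and middle probe sets of pyruvate carboxylase. The same held for the 3′ and middle probe sets of the transferrin receptor. The log2 level of the 3′ probe set was 13.5 ± 0.05 (SD, n = 3) in the exposed females and 14.4 and 14.2 in the males, a log2 difference of -0.82 (95% interval -1.19 to -0.45). For the middle probe set the log2 difference was -1.06 (95% interval -1.51 to -0.62), and for the 5′ probe set it was -1.21 (95% interval -1.87 to -0.55). None of the 3 passed limma's test over all probe sets (adjusted p = 0.131, 0.112 and 0.176 from the 3′ end to the middle and the 5′ end). Within the 16 probe sets of endogenous control transcripts, a list taken up after the table was seen, Gapdh gave the only 3 that passed limma's test adjusted over the list alone (adjusted p = 0.0153, 0.0153 and 0.0245).

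The other named transcripts did not pass. Pyruvate carboxylase, which makes oxaloacetate from pyruvate, had log2 differences of -0.46, -0.38, -0.44 and -0.46 at its 4 probe sets, with limma adjusted p over the list from 0.175 to 0.259. Its highest level at the 3′ probe set was 8.12 in unexposed male 2, against 7.48 in unexposed male 1 and 7.34 ± 0.24 (SD, n = 3) in the exposed females. The groups overlapped there, with exposed female 2 at 7.49, but not at the 5′ and middle probe sets. At the 5′ probe set the exposed females stood at 6.50, 6.23 and 6.41 and the males at 6.56 and 6.96. The transferrin receptor, which takes iron into cells, had log2 differences of -0.35, -0.22 and 0.02 at the 3′, middle and 5′ probe sets. Beta-actin, a cytoskeletal protein, had log2 differences of 0.14, 0.29 and -0.15 in the same order. For 18S ribosomal RNA the differences were 0.17, -0.04 and -0.14, and for the B1 and B2 repeat probe sets they lay between 0.11 and 0.18. The 18 hybridisation controls, which are added to every sample before hybridisation, differed between the groups by a mean of -0.01 and by at most 0.16 on the log2 scale. The gap between 3′ and 5′ probe sets, a sign of RNA integrity, did not move one way over the 5 transcripts. For Gapdh it was 0.85, 0.95 and 0.27 in exposed females 1, 2 and 3 and 0.36 and 0.24 in the males. For beta-actin it was 1.27, 1.63 and 0.86 in the exposed females and 0.99 and 0.93 in the males. For the transferrin receptor the gap was narrower in every exposed tumour (1.35, 1.68 and 1.45) than in the males (1.80 and 1.92), and its 5′ probe set was near the low end of the scale. For pyruvate carboxylase the gap differed by a mean of -0.08 in the exposed tumours. For 18S ribosomal RNA it was -0.07, -0.01 and -0.49 in the exposed females and 0.30 and -1.31 in the males. The mean difference of 0.32 for 18S ribosomal RNA thus rested on unexposed male 2.

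**Figure D3:**
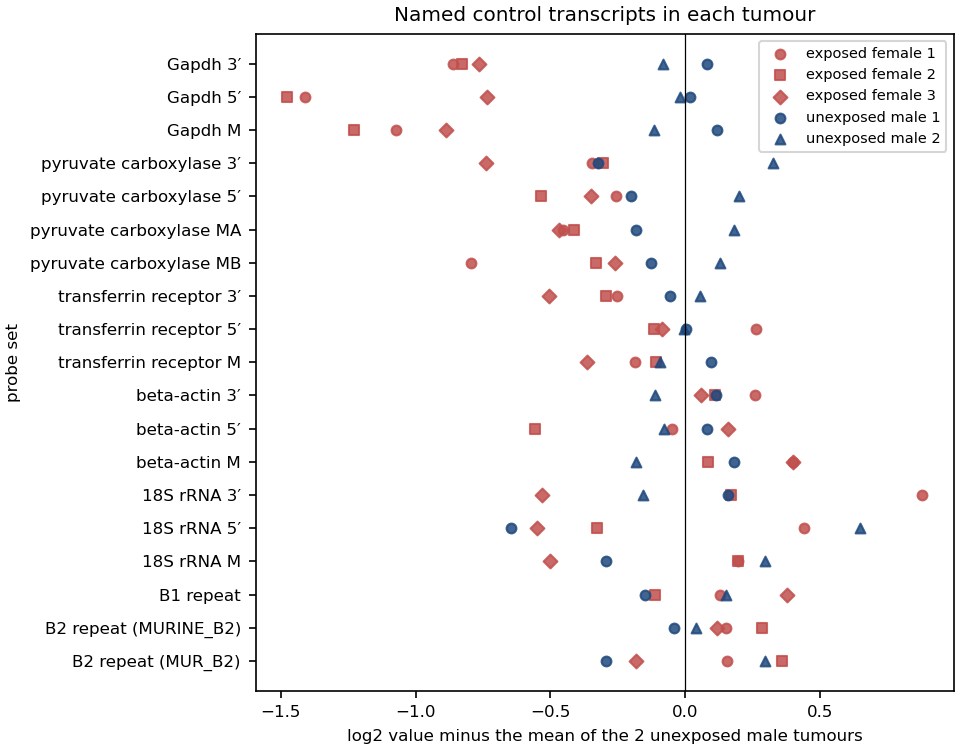
Level of each named control probe set in each tumour, as the log2 value minus the mean of the 2 unexposed male tumours (horizontal axis); red symbols are exposed females and blue symbols unexposed males. The 3 Gapdh probe sets lie below both males in all 3 exposed females, while beta-actin and 18S ribosomal RNA overlap between the groups. The 5′ and middle probe sets of pyruvate carboxylase and the 3′ and middle ones of the transferrin receptor also lie below both males, with smaller differences.

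The last comparison was between tumours of the same group. Most transcripts varied little, with a median within-group SD of 0.229 log2 units, but 1312 probe sets (2.91%) had a within-group SD of at least 1, and 244 had at least 2. Variation lay mainly among the exposed females. Among these, 1575 probe sets spanned 4-fold or more and 330 spanned 16-fold or more, against 117 and 10 between the unexposed males, although a range over 3 tumours is wider than a difference between 2. Pair by pair, 657 to 1016 probe sets were 4-fold or more apart between exposed females. The 10 probe sets that were 16-fold or more apart between the males included 8 at which unexposed male 2 lay nearer the exposed mean than unexposed male 1 did. The widest of them, 1427262_AT, chosen after its values were seen, had a log2 level of 4.67 in unexposed male 1 and 11.5 in unexposed male 2, against 12.3, 13.1 and 12.7 in the exposed females. The same pattern was seen at 1427263_AT, also chosen after its values were seen, with 4.45 in unexposed male 1, 10.1 in unexposed male 2 and 10.4, 11.6 and 11.2 in the exposed females. Which genes these probe sets measure, and whether the label or composition of unexposed male 2 accounts for them, was not examined. Some of the 10 may measure a single transcript, so 1427263_AT need not be an independent repeat of 1427262_AT. Without exposed female 3, the number of probe sets with a within-group SD of at least 1 was 873.

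Transcripts that set a single tumour apart were unevenly distributed. Exposed female 1, from the mouse of 13 months, had 136 probe sets at least 8-fold above the other 4 tumours and 0 at least 8-fold below them. The 136 became 49 when only probe sets with a log2 value of 6 or more in at least 2 arrays were kept, a filter that removes those high in a single tumour. Exposed female 3 had 20 above and 32 below. Exposed female 2 had 18 above and 0 below, unexposed male 1 had 7 and 3, and unexposed male 2 had 2 and 1. Of the 32 probe sets at least 8-fold below in exposed female 3, 18 were among the 210 that were 8-fold or more lower in the exposed females as a group. This overlap is partly built in. The 32 lie below both males by definition, and exposed female 3 is part of the exposed mean. With 1 tumour of 13 months, age was not tested.

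**Figure D4:**
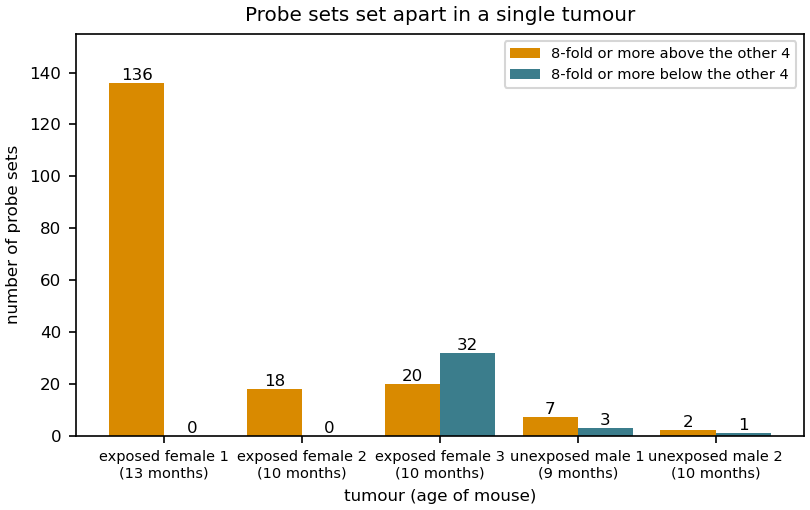
Number of probe sets (vertical axis, from 0) that were at least 8-fold above (orange) or below (teal) all 4 other tumours, for each tumour, with the age of the mouse in months. Exposed female 1 has 136 above (49 when only probe sets with a log2 value of 6 or more in at least 2 arrays are kept), and exposed female 3 has 32 below.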

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

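The measures in this part were chosen after the data were seen. Across the 5 tumours, which share a genotype, 29 measures (array summaries, named control transcripts, 3′ to 5′ gaps and counts of probe sets set apart) were searched for a tumour far from the rest by Dixon's gap test with a critical value of 0.71; chance passes about 1 in 20 for normal values, and counts are not normal. The first measure that passed was the number of probe sets at least 8-fold above the other 4 tumours, 136 in exposed female 1 against 20 in the next tumour (gap over range 0.866); the 136 became 49 when only probe sets with a log2 value of 6 or more in at least 2 arrays were kept. The second was the number at least 8-fold below the other 4, 32 in exposed female 3 against 3 in the next (gap over range 0.906). No named control transcript, array summary or 3′ to 5′ gap passed.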

How the results depend on the processing

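No paired analysis was possible because the labels give the groups no shared replicate numbers. Under the scalings, filters, variance model and array weights, the number of called probe sets ranged from 215 (arrays centred on their medians) to 316 (array weights) against 241 as reported, and 213 to 241 of the reported calls were shared under each. Array weights raised the calls higher in exposed females from 20 to 41. Leaving out each tumour in turn gave 0 to 257 calls, 0 to 33 higher (2, 16 and 33 without exposed females 1, 2 and 3) and 0 to 224 lower; the 0 came from leaving out either male, which leaves 1 male, and 99, 83 and 184 reported calls were shared without exposed females 1, 2 and 3. Probe sets 8-fold or more higher in exposed females numbered 16 to 107 over the same omissions, and those with a within-group SD of at least 1 numbered 873 to 1724. The distance difference kept its sign, from 0.01 to 0.0299 over the omissions, and p was 0.2 with the 1000 most variable probe sets. The 4 named probe sets kept their direction throughout and lost their call without either male (adjusted p 0.0591 to 0.225), while their log2 differences without unexposed males 1 and 2 stayed near the reported ones, at -6.42 and -7.00 for 1426438_AT, -6.99 and -6.60 for 1447713_AT, 4.24 and 4.20 for 1453351_AT and 2.67 and 2.30 for 1446234_AT; 1446234_AT also lost it without exposed female 1 (0.0604) or exposed female 2 (0.0557). The 3 Gapdh probe sets stayed lower in exposed females and did not pass over all probe sets under any of these settings (adjusted p 0.0547 to 0.719). Keeping only probe sets at 6 or more in at least 2 arrays lowered the 136 probe sets of exposed female 1 to 49, by construction, since it removes those high in a single tumour. The cause of the other changes was not tested.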

Other observations

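The tests in this part were chosen after the data were seen, except the count over other splits of the tumours, which was planned. Most transcripts that were low against the males in a pair of exposed tumours were also low in the remaining one. Each exposed tumour was placed on a scale from 0, the mean of the other 2 exposed tumours, to 1, the mean of the males, using probe sets picked without it. At probe sets 8-fold or more lower in the other 2, exposed female 1 lay at a median of 0.13 (221 probe sets, 12 nearer the males), exposed female 2 at 0.10 (237, 30 nearer the males) and exposed female 3 at -0.20 (178, 0 nearer the males). With no difference between the groups, 100 simulated draws gave a median of 0.50, from 0.22 to 0.72 over the draws. At probe sets 8-fold or more higher in the other 2, exposed female 1 lay at a median of 0.70 (16 probe sets, 9 nearer the males), exposed female 2 at 0.65 (65, 36 nearer the males) and exposed female 3 at 1.05 (107, 102 nearer the males). The same draws gave a median of 0.53 for these, from 0.28 to 0.80 over the draws. In the same way, unexposed male 2 lay at 0.87 at the 251 probe sets 8-fold or more higher in unexposed male 1 than in the exposed tumours, and unexposed male 1 lay at 1.02 at the 192 picked from unexposed male 2. With no difference between the groups the draws gave a median of 0.25 for a held-out male, from 0.09 to 0.43 over the draws. All draws gave each probe set the same spread in every tumour, whereas the real variation lay mainly among the exposed females. Probe sets high in exposed female 1 alone, 136 at 8-fold or more, can enter the picks of rises made without exposed female 3. The draws therefore cannot decide whether any of these positions departs from no difference between the groups.

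The 241 calls between the groups were set against chance and scaling. Only 1 of the 10 splits of the tumours into 3 and 2, the real one, gave as many, and the highest other split gave 2. The other splits mix the groups, so a group difference widens their residual spread and lowers their counts. The real split also sets apart the most similar pair of tumours. Besides, 10 splits are too few for a share under 0.05. A uniform scaling difference between arrays that remained after RMA is argued against by the 18 hybridisation controls. Their largest log2 difference between the groups was 0.158, while the smallest called difference was 1.25. These controls lay between 8.67 and 14.3, so they cannot show a difference at low levels or in steps before they are added. The interquartile range was wider in the exposed females (3.05, 3.02 and 3.20) than in the males (2.91 and 2.78). A second quantile normalisation kept 234 of the 241 calls. Sex, tamoxifen and the tissue of origin stay open, and the design cannot separate them.

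The 210 probe sets that were 8-fold or more lower in the exposed tumours could come from normal tissue taken with the male tumours. A single tissue of fixed composition would shift them all by one amount between the 2 males only where the tumour cells added little signal. That signal was not measured. The log2 difference between the males had an SD of 1.16 over these probe sets. In 10000 random sets of the same male level the median SD was 0.442 (95% interval 0.385 to 0.510). The 210 were picked on a large difference from the male mean, so probe sets very high in a single male can enter and widen this SD. An example is 1426650_AT, at 11.9 in unexposed male 1 and 5.65 in unexposed male 2. The random sets were not picked in that way, so the comparison cannot decide whether a single tissue was the whole source. Several tissues, or a tissue whose composition differs, also stay open because no probe set is named here. Lower RNA integrity in the exposed tumours cannot be told apart from the other explanations. The mean 3′ minus 5′ gap was higher in the exposed tumours for Gapdh (by 0.389) and for beta-actin (by 0.292). For 18S ribosomal RNA it was 0.317 higher, but the males stood at 0.30 and -1.31, with every exposed gap between them. The transferrin receptor gap was lower in every exposed tumour (mean difference -0.37), but its 5′ probe set was near the low end of the scale. That of pyruvate carboxylase differed by -0.08. Exposed female 3, whose Gapdh gap lay within the male range, was the exposed tumour farthest from the males at the falls, with a median position of -0.20. These values come from 5 transcripts that disagree, and the positions of the 210 probe sets along their transcripts are unknown.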
